A study of Caenorhabditis elegans with 4 samples.

How the data were processed

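Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against ZIM-1 was carried out in Caenorhabditis elegans of the strain fem-2(b245). Per the labels, the animals were young adult hermaphrodites with a germline, grown at 20 °C. Frozen worms were ground and fixed in 1% formaldehyde for 10 min, and the chromatin was sheared by sonication, per the labels' protocols. The 4 samples form 2 groups: 2 ZIM-1 ChIP libraries and 2 input libraries made from genomic DNA without immunoprecipitation. The titles number both groups 1 and 2, and nothing in the labels says whether the replicates came from separate worm cultures, so the spread between them may be technical.

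The processed data used here were 3 peak lists: 1 for each ChIP replicate and 1 for the whole series. Each gives the first and last base of every peak and 1 score per peak, on WormBase release WS220, per the file headers. The submitters' processing notes name the aligner BWA and the build ce10, which is the UCSC name of WS220. The source column of the deposited replicate lists names MACS as the peak caller, and that of the deposited series-wide list names MACS v2. Whether the series-wide list was called on pooled reads, which control was used and which settings applied is not given in the sources used here. No values of the input libraries were analysed here.

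The deposited score is the authors' value from their peak caller, and no header says which quantity it is. In the replicate lists it began at 50 and 50.01, and 223 and 222 peaks were tied at 3100. The highest scores there lay above the tie, at 3223.52 and 3230.05. In the series-wide list it ran from 1.3 to 174.44, with 78 peaks tied at the highest value. Scores were therefore compared only within a list. The exception was the correlation of scores, by rank and on the log10 scale, across overlapping peaks of the replicate lists. Read depth is unknown for all libraries, so intervals below treat each peak as 1 count and cover counting error only.

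Everything that follows was computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Peaks were called shared when they overlapped by at least 1 bp. Overlap between replicates was compared with 100000 random circular shifts of the replicate 2 list within each chromosome, in a one-sided permutation test; a shift keeps peak widths, counts per chromosome and clustering. Scores of shared and unshared peaks were compared by a two-sided permutation test of the difference in medians with 100000 resamples. Densities were given per Mb with exact Poisson intervals at 95%, and shares with exact Clopper-Pearson intervals. Chromosome lengths were taken as the last base of the last peak in any list. Chromosomes II and III were compared with the other 4 nuclear chromosomes by an exact permutation test over all 15 splits, which cannot give a p below 0.067. The share of X was tested with a two-sided exact binomial test. Peak midpoints within 2 Mb of each of 12 chromosome ends were compared with 100000 circular shifts in a two-sided permutation test, adjusted by the Benjamini-Hochberg method over the 12 ends. Windows of 100 kb were tested for an excess of peak midpoints over the mean of their chromosome by an exact Poisson test, adjusted over all 1005 windows. The series-wide list was the main list for location, and the mitochondrial genome was left out of these comparisons.

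The comparisons, the settings and the rule for naming sites were chosen before the data were examined. Named sites were the 20 peaks with the highest score in the series-wide list among those found in both replicates, with ties broken by width, the first such peak of each chromosome, and the 10 windows with the most peaks. Alternatives were a stricter overlap, the higher-scoring 50% of a list, equal numbers of peaks, each replicate list alone, the peaks found in both replicates, and other window and end sizes.

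The procedures were tested on simulated lists with peaks placed uniformly at random along each chromosome, unlike the clustered peaks of the data. The outcomes hold for that setting alone. For the comparison of replicates, 1 of 20 pairs of independent lists gave p under 0.05, and 20 of 20 pairs did when 10% of the smaller list was placed on peaks of the larger. For the windows, 90.2% of 400 windows made 3 times as dense were called. For the chromosome ends, 200 peaks were added within 2 Mb of the left end of II, about as many as a uniform list holds there. Of 20 such lists 13 were called, so this test can miss moderate and large excesses. Gene content and sequence were not analysed, because the gene table used here is of assembly WBcel235, a different build from that of the peak lists, and coordinates were not carried over between builds.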

Results

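ZIM-1 is a zinc finger protein of C. elegans known for binding the meiotic pairing centers of chromosomes II and III, the regions at which homologous chromosomes pair and start synapsis. Its binding was profiled by ChIP-seq in fem-2(b245) worms; fem-2 acts in the sex determination pathway. The ChIP group held 2 replicates and the input group held 2 replicates. Replicate 1 had 5552 peaks with a median width of 481 bp (interquartile range 359 to 750), covering 3.97 Mb of the nuclear genome. Replicate 2 had 2887 peaks with a median width of 574 bp (interquartile range 436 to 819), covering 2.43 Mb of it. The series-wide list held 9439 peaks with a median width of 288 bp, its nuclear peaks covering 4.45 Mb, or 4.43% of the nuclear genome. All coordinates are on WS220.

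The first comparison asked whether the ChIP replicates marked the same sites. Most of the shorter list recurred: 2429 of the 2886 nuclear peaks of replicate 2 overlapped a peak of replicate 1, a share of 84.2% (95% interval 82.8 to 85.5). In the other direction 43.9% of the replicate 1 peaks overlapped a peak of replicate 2 (42.6 to 45.2). Circular shifts of the replicate 2 list gave 241 shared peaks on average and 742 at most, so the overlap was 10.1 times the chance level (permutation test, one-sided, p = 1e-05, the smallest that 100000 shifts can give). With shifts of only 10 to 100 kb, a null model chosen after seeing the data that keeps the broad density of peaks, chance overlap was 314 peaks and the ratio was 7.74.

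Peaks found in both replicates scored higher than the rest. In replicate 1, shared peaks had a median score of 382 and unshared peaks 98.9, a difference of 283 (permutation test, two-sided, p = 1e-05). In replicate 2 the medians were 259 and 93.5, a difference of 165 (permutation test, p = 1e-05). Shared peaks were also wider, with median widths of 631 against 402 bp in replicate 1 and 598 against 450 bp in replicate 2. A wider peak meets an overlap of 1 bp more easily. Both tests treat peaks as independent although peaks cluster, so they overstate the precision. Among the highest-scoring 10% of replicate 1 peaks, 97.5% were found in replicate 2 (95.8 to 98.6), against 10.8% of the lowest-scoring 10% (8.34 to 13.7). The matching shares of replicate 2 peaks found in replicate 1 were 97.2% (94.6 to 98.8) and 64.7% (58.9 to 70.2). Across 2429 overlapping pairs, the scores of the replicates had a Spearman rho of 0.72 and a Pearson r of 0.75 on the log10 scale (permutation test, both p = 1e-05). These are correlations across peaks, which are not independent replicates, and rho was 0.65 over the 2146 pairs with both scores below the tied value of 3100.

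**Figure D1:**
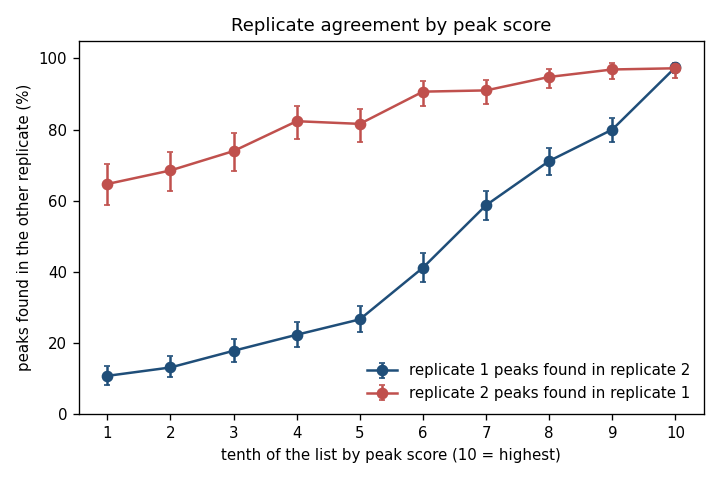
Share of peaks of each replicate that overlapped a peak of the other (y axis, percent), by equal parts of the list ranked by score (x axis, 10 parts, 10 = highest); points are shares and bars are 95% Clopper-Pearson intervals. The replicate 1 line climbs from 10.8% to 97.5%, and the replicate 2 line from 64.7% to 97.2%.

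The series-wide list was then set against the replicate lists. It contained 95.3% of the replicate 1 peaks and 98.3% of the replicate 2 peaks. Of its 9439 peaks, 2443 were found in both replicates (25.9%), 3132 in replicate 1 alone (33.2%), 505 in replicate 2 alone (5.35%) and 3359 in neither (35.6%). The median series-wide score was 40.4 for peaks found in both replicates, 7.54 for those in replicate 1 alone, 11.02 for those in replicate 2 alone and 4.83 for those in neither. Median widths were 584 bp for peaks found in both and 195 bp for those in neither. How the series-wide list was made is not given, so no test was made.

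The strongest sites lay on all 6 nuclear chromosomes. All 78 peaks tied at the highest series-wide score overlapped a peak in both replicates. Their median width was 1754.5 bp, against 287 bp for the other peaks. Of these 78 peaks, 25 were on IV, 20 on V, 14 on II, 10 on X, 5 on III and 4 on I. The 20 named sites, the widest of the tied peaks, ranged from 2372 to 7242 bp, and each met a replicate 1 peak and a replicate 2 peak with the score of 3100. The widest lay on chromosome II from 1429887 to 1437128. It was followed by a site on III from 185846 to 192294 and a site on V from 18075307 to 18081409. The widest tied site of chromosome I spanned 13609938 to 13615735, that of IV 14475797 to 14481290, and that of X 13794601 to 13797860. Chromosome IV held 8 of the 20 named sites, III held 4, V held 3, I and II held 2 each, and X held 1. On III the other 3 sites were also near the left end, starting at 77812, 84066 and 424283. The other site on II started at 855851.

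The known association of ZIM-1 with chromosomes II and III raises the question of whether peaks were denser there. Chromosome III had the highest density, 136.5 peaks per Mb (95% counting interval 130.4 to 142.8), and it was also the densest in replicate 1, with 77.6 peaks per Mb, and in replicate 2, with 47.2 peaks per Mb. Chromosome II had 96.3 peaks per Mb (91.5 to 101.4), between V with 81.1 and IV with 105.2, and chromosome I had 112.4. The place of II differed between lists. Among peaks found in both replicates it came next after III, with 28.9 peaks per Mb against 40.8. It also came next after III in replicate 2, with 32.8. In replicate 1 it had 58.5, below IV with 64.02 and I with 62.8. The mean of II and III was 116.4 peaks per Mb against 86.7 for the other chromosomes, a ratio of 1.34 that did not stand apart from other pairs of chromosomes (exact permutation test, two-sided, p = 0.4). Among peaks found in both replicates the ratio was 1.71 (exact permutation test, p = 0.13). Among the 78 peaks tied at the highest score, a set added after seeing the data, it was 0.80.

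Chromosome X was the sparsest in the series-wide list and in each replicate. It held 851 of 9436 nuclear peaks, or 9.02% (8.45 to 9.61), on 17.7% of the sequence. Its density was 48.0 peaks per Mb (44.9 to 51.4) against 103.99 for the autosomes together, a ratio of 0.46 (exact binomial test, two-sided, p = 5.1e-126). The ratio was 0.45 in replicate 1 and 0.40 in replicate 2. Among the 78 peaks tied at the highest score X held 10 (12.8%), more than III with 5 or I with 4. X was therefore not the sparsest chromosome in that set. Peaks cluster, so the binomial test overstates the precision. A setting added after seeing the data took 1 Mb bins as the unit. The 17 bins of X had a mean of 46.7 peaks and the 80 autosomal bins 103.9 (permutation test, two-sided, p = 1e-05). This test shuffled bins across chromosomes as if they were independent, although bins of 1 chromosome may share its level and X is 1 chromosome. Its p therefore overstates the precision as well.

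**Figure D2:**
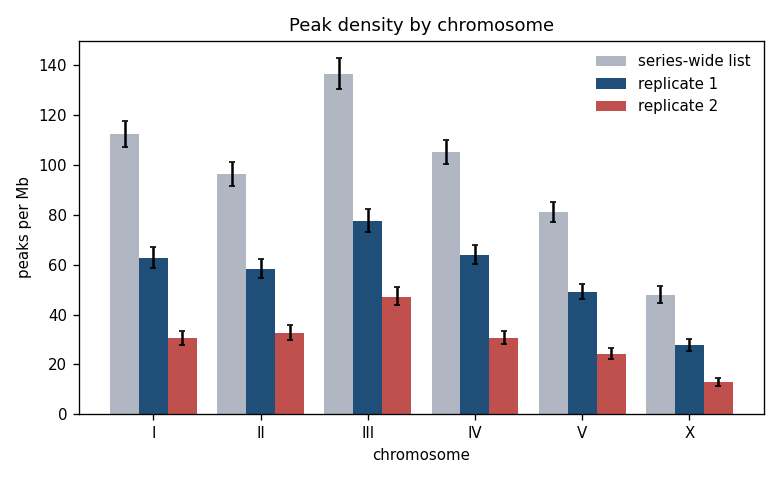
Peaks per Mb (y axis) on each nuclear chromosome (x axis) for the series-wide list and each ChIP replicate; error bars are exact 95% Poisson intervals. Chromosome III is highest in each list and X lowest, at 136.5 and 48.0 peaks per Mb in the series-wide list.

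Pairing centers lie toward 1 end of each chromosome, so both ends of every chromosome were examined. Within 2 Mb of the left end of III there were 239.5 peaks per Mb against 119.1 on the rest of that chromosome, a ratio of 2.01. The left end of X had a ratio of 2.59, the right end of V 1.84, the left end of IV 1.70 and the left end of II 1.67. The lowest ratio was 0.84, at the left end of V. Over 1 Mb the left end of X had 3.32, the left end of IV 1.43 and the left end of III 1.26, the right end of V fell to 1.06, and on II the right end, with 1.38, was denser than the left, with 1.27. Over 2 Mb no single end passed the permutation test: the adjusted p was 0.28 at each of these 5 dense ends, and 0 of 12 ends had an unadjusted p under 0.05. The test can miss large excesses, so this does not show that these ends match the rest of their chromosomes. In replicate 2 alone the left end of X passed, with a ratio of 2.76 (permutation test, adjusted p = 0.035), and in replicate 1 alone its ratio was 2.65 with an adjusted p of 0.24 (permutation test). Among peaks found in both replicates the left ends had 3.22 on III, 3.10 on X and 2.23 on II, and the right end of V 1.79. The left end of IV fell to 1.11 there. The adjusted p was 0.26 at the first 4 of these ends and 0.84 at that of IV (permutation test).

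At a finer scale, peaks were clustered. Of 1005 windows of 100 kb, 88 held more peaks than the mean of their chromosome predicts (exact Poisson test, Benjamini-Hochberg adjusted): 22 on V, 17 on II, 17 on IV, 15 on III, 9 on X and 8 on I. The window with the most peaks was on III from 1.5 to 1.6 Mb, with 56 peaks where 13.7 were expected (adjusted p = 1.6e-15 by the Poisson test). Of these peaks 32 were found in both replicates. Replicate 2 itself had 30 peaks there, so several series-wide peaks may have met the same replicate peak. The window on III from 1.8 to 1.9 Mb held 54 peaks, that on II from 1.3 to 1.4 Mb 52 where 9.63 were expected, and that on V from 18 to 18.1 Mb 48 where 8.11 were expected. The first 0.1 Mb of X held 47 peaks where 4.80 were expected, the largest excess of the 10 named windows, at 9.79 times. The other named windows were on III from 1.1 to 1.2 and from 1.6 to 1.7 Mb, on IV from 0.8 to 0.9 and from 2.3 to 2.4 Mb, and on V from 19 to 19.1 Mb, with 38 to 44 peaks each. The peak counts of windows varied 3.20 to 6.83 times more than a Poisson process within each chromosome. Against a negative binomial background with that spread, added after seeing the data, 0 windows passed and 42 had an unadjusted p under 0.05. From the replicate 1 list alone 47 windows were called, 42 of them among the 88, and from the replicate 2 list alone 36, 32 of them among the 88.

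**Figure D3:**
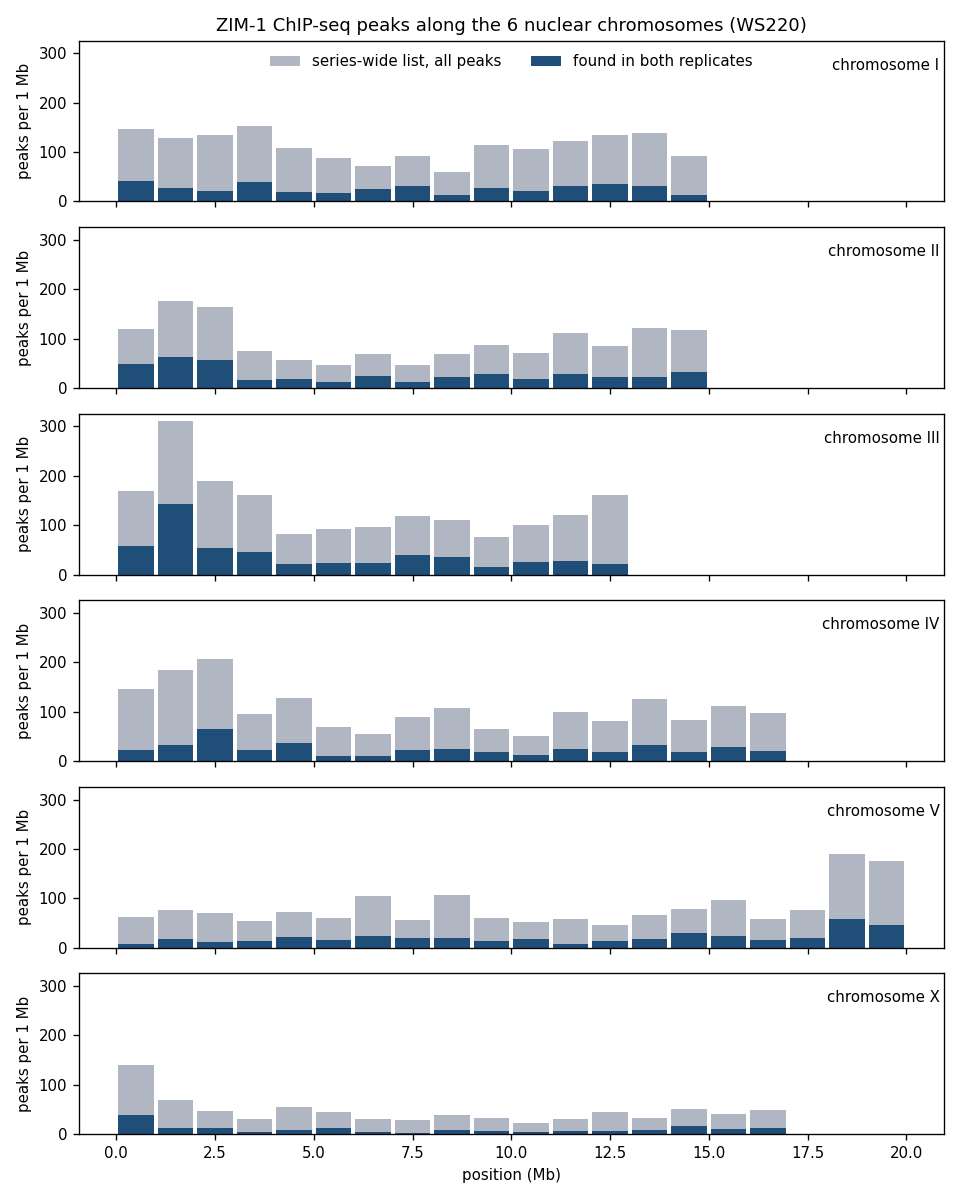
Peaks in complete 1 Mb bins (y axis) along each nuclear chromosome (x axis, Mb); light bars count all series-wide peaks and dark bars those found in both replicates, and the incomplete last bin of each chromosome is not drawn. The tallest bin is the second of III, with 310 peaks, 142 of them found in both replicates.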

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

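All tests of this part were chosen after the results were seen, except that of the strong sites of replicate 2.

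The mitochondrial genome, which was left out of every comparison of location, carried peaks in 2 of the 3 lists. In the series-wide list 3 peaks covered 13511 bases of it, with scores of 42.0, 41.5 and 14.6. In replicate 2 a single peak covered 13515 bases, from 2 to 13516. Replicate 1 had 0 peaks there, and no control values were analysed here.

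In the series-wide list the first peak began at base 1 on 6 of 6 chromosomes, with scores from 14.9 to 43.6, and each overlapped a peak of both replicates. The last series-wide peak of each chromosome lay beyond the last peak of both replicates, so 6 of 6 were missing from both replicate lists, although 97.8% of the 1202 series-wide peaks in their range of scores were found in a replicate. Chromosome lengths were taken from the peaks and not from the assembly, so how far these last peaks lie from the true ends was not examined here. Different treatment of the last bases by the peak caller versions stays open. For the first bases, a candidate explanation is sequence present in more copies in the worms than in the assembly, as in telomeres; a wide peak at the right end of I, from 15060224 to 15071363, lies where the ribosomal DNA repeats of C. elegans are found, and 2 lists had mitochondrial peaks, but without input values this stays open.

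Replicate 2 had fewer peaks than replicate 1. A separate set of strong sites in replicate 2 is argued against by the 97.2% of its highest-scoring 10% that were found in replicate 1. Lower depth or lower enrichment in replicate 2 stays open: the share found in the other replicate rose with score in both lists, from 10.8% to 97.5% in replicate 1 and from 64.7% to 97.2% in replicate 2, so the rise does not tell which library was weaker. Read depth is unknown, and a biological difference between the replicates was not tested.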

How the results depend on the processing

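No paired analysis was possible because peak lists were analysed for the ChIP group alone, so no ChIP value had an input partner with the same number. The overlap of the replicates stayed above chance in each of 5 alternatives, between 70.03% and 89.0% of the shorter list, and the score differences, the score correlation and the deficit on X kept their direction and side of the threshold wherever an alternative had a test. The share of series-wide peaks found in both replicates was 21.7% when at least 50% of both peaks had to overlap and 27.6% in the higher-scoring 50% of each list. The ratio of II and III to the other chromosomes was between 1.33 and 1.71 in both replicate lists, the peaks found in both, the higher-scoring 50% and covered bases; in 2 settings added after seeing the data it was 1.17 with the sparse X left out and 0.80 among the 78 peaks tied at the highest score, for which the cause was not tested. Its 15 splits, or 10 without X, cannot give a p under 0.05. The number of chromosome ends past the threshold in the series-wide list was 0 over 1 Mb and over 3 Mb. Over 2 Mb it was 0 or 1 from single replicates, and 1, the left end of X, in the higher-scoring 50% of the list. Over 3 Mb the left end of X also passed in replicate 2, with a ratio of 2.37 (permutation test, adjusted p = 0.020). In replicate 1 its ratio was 2.15 with an adjusted p of 0.31 (same test). The count of 88 clustered windows rose to 109 with 50 kb windows, of which there are more, and fell to between 36 and 47 with single replicates, to 27 with peaks found in both replicates and to 46 in the higher-scoring 50%, where fewer peaks enter, to 52 with 200 kb windows, of which there are fewer, and to 0 against the negative binomial background, whose spread includes the clusters. The tests of gene features and of sequence words were not run, since no genome or annotation of the build was used here. The unknown read depth limits what a missing peak shows.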

Other observations

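The tests of this part were chosen after the results were seen. They include the joint test of the denser 2 Mb ends over 6 chromosomes in the series-wide list, which averages single-end ratios already seen. Only its comparison with circular shifts was unknown when it was specified. Its p therefore does not carry the weight of a test planned before the data were examined.

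Counted as independent draws, the 78 peaks tied at the highest score were spread differently over the chromosomes than peaks in general. Peaks cluster, so the tests below overstate the precision. Chromosome IV held 25 of them (32.1%) and 19.5% of all nuclear peaks (Fisher's exact test, two-sided, adjusted p = 0.018 over 6 chromosomes). Chromosome III, the densest, held 5 of the 78 (6.41%) against 19.9% of all peaks (Fisher's exact test, adjusted p = 0.0047), and chromosome I held 4 (5.13%) against 18.0% (adjusted p = 0.0047, same test). The shares of II, V and X did not differ past the threshold, with adjusted p of 0.53, 0.15 and 0.28. In the higher-scoring 50% of the list, of 4717 nuclear peaks, the shares of III and IV moved the other way, to 21.8% and 17.8%, and that of I was 17.2%; these were not tested.

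Peaks inside the 88 clustered windows were found in both replicates somewhat more often than other peaks, 28.7% of 2328 (26.9 to 30.6) against 24.96% of 7108 (24.0 to 26.0; Fisher's exact test, two-sided, p = 0.00035). Their median score was 9.27 against 7.58 (permutation test, two-sided, p = 1e-05), and their median widths were 292 and 287 bp (permutation test, p = 0.45). These tests count each peak as independent although peaks cluster, so they overstate the precision. By chromosome, the share found in both ranged from 21.6% on X to 30.0% on II. The tests made no allowance for chromosome or for how many replicate peaks lay nearby.

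Over the 6 nuclear chromosomes, the mean ratio of the denser 2 Mb end in the series-wide list was 1.85, against 1.20 in circular shifts (permutation test, one-sided, p = 0.0019), and p was 0.045 over 1 Mb and 0.0003 over 3 Mb; this argues against random placement of the clusters, although in that list 0 of 12 single ends passed after adjustment over 1, 2 or 3 Mb, and 1, 0 and 3 had an unadjusted p under 0.05. Weak calls in a single library are argued against over 2 Mb by the mean of 2.13 among peaks found in both replicates, against 1.301 in shifts (permutation test, p = 0.00518), and over 3 Mb (p = 0.00034), but over 1 Mb the p was 0.054. A property shared by both ends, such as repeats of the arms, stays open. The sparser 2 Mb end had a mean ratio of 1.10 in the series-wide list, against 0.84 in shifts (permutation test, p = 0.0083). In that list p was 0.072 over 1 Mb and 0.0104 over 3 Mb (same test). Over 2 Mb it was 0.0062 in replicate 1, 0.084 in replicate 2 and 0.18 among peaks found in both replicates. Over 3 Mb it was 0.00803, 0.057 and 0.092 in the same order (same test). A joint test with II and III left out covered the other 4 chromosomes. The series-wide mean ratio of the denser 2 Mb end was then 1.85, against 1.196 in shifts (permutation test, p = 0.0102). The p was 0.052 over 1 Mb and 0.0031 over 3 Mb (same test). Among peaks found in both replicates it was 0.05002 over 2 Mb, 0.063 over 1 Mb and 0.0043 over 3 Mb (same test). The series-wide excess over 2 and 3 Mb was therefore not confined to II and III. Sequence peculiar to the dense ends, which may raise peaks without binding, was not tested. Neither were binding by ZIM-1 and recognition of related pairing center proteins by the antibody, since no input values, genome or second antibody were analysed here.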
